A study of Homo sapiens with 90 samples.

How the data were processed

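Total RNA of HepaRG cells was used at 10 ng per library, with reverse transcription by template switching, PCR to double-stranded cDNA and tagmentation, per the labels' protocols. Reads were handled with BWA 0.7.4.4, and the genome builds mm10 and hg38 are named, per the submitters' processing notes, which do not say what each build was used for. The deposited values are raw counts per gene, whole numbers that are not scaled between libraries, with gene symbols in the file headers and rows. The rule for counting reads, the use of molecular identifiers, the strand and the annotation version are not stated in the labels or the file headers. Of 28307 deposited symbols, 27200 (96.1%) were found as symbols in a RefSeq gene table. Because the counting rule is not given, values of near-identical or overlapping genes are uncertain where reads could be split between them, such as CYP2D6 and CYP2D7, ADH1A and ADH1C, ORM1 and ORM2, the UGT2B genes, the metallothioneins and the ribosomal protein genes. Coordinates are those of the RefSeq gene table on hg38. Runs of T and A were searched in transcript sequences of GENCODE release 29.

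From the deposited counts, edgeR 4.0.16 in R 4.3.3 was used to fit a model with 1 mean for each of the 30 groups to all 90 libraries, with TMM scaling factors, genes kept by filterByExpr on the groups and a robust quasi-likelihood fit with 60 residual degrees of freedom. The common dispersion was 0.0435. Totals of the 87 usable libraries ran from 723391 to 3882866 counts, with a median of 1935150. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over the 12125 genes tested, and 3172 of the 28307 genes in the file had no count. CPM, counts scaled to a common library total with the TMM factors, and all log2 and fold values were computed here from the deposited counts. The 3 nearly empty libraries, those under 0.25 times the median total, stayed in the fit and were left out of group means and SDs. There were 10 comparisons between groups and 3 differences of effects. Ratios of CYP2D6 counts have 95% exact intervals that cover counting error, and a fold against a group without counts is given against a floor of 3 counts over the group.

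Gene lists, 25 in number, were tested in each comparison with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01, adjusted over the 24 lists with at least 3 tested members, and again with a correlation estimated from the residuals. The lists were other P450 enzymes, phase II conjugation, hepatic transporters, hepatocyte secreted proteins, liver transcription factors, biliary and progenitor markers, foetal liver markers, cell cycle, mesenchymal and matrix genes, stellate, fibroblast and endothelial markers, macrophage and leukocyte markers, unfolded protein and amino acid stress, heat shock, NRF2 targets, p53 targets, interferon response, inflammation and acute phase, bile acid synthesis and conjugation, sterol synthesis, urea cycle, amino acid and glucose metabolism, fatty acid oxidation and ketogenesis, lipid synthesis, metallothioneins, mitochondrially encoded transcripts and ribosomal proteins. Named genes were CYP2D6, the 8 largest rises and 8 largest falls among called genes with a mean of at least 20 CPM and the same sign in every pair of group means, and the 3 members with the smallest p of up to 4 lists with the lowest camera p. For differences of effects the 5 largest were named, and a fixed panel of genes was followed over all groups. Not every gene that meets the rule is reported here. Comparisons, gene lists, the rule for named genes and the first 9 kinds of alternative below were set before the data were examined.

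Alternatives to these choices were RLE scaling factors, no filter on low counts, a mean count of at least 10, the replicate letter as a block, leaving out replicate a, b or c of every group, leaving out the 3 nearly empty libraries, a fit to the compared libraries only, DESeq2 1.42.0 and the estimated correlation. Chosen after seeing the data were the component score as a covariate without the nearly empty libraries, RLE and DESeq2 without the nearly empty libraries, leaving out the 2 parental libraries with 10 CYP2D6 counts each, leaving out parental progenitor day 14 replicate a, and 3 further comparisons. The component is the first principal component of the residuals within groups, and its score is the mean log2 CPM of the 100 genes that follow it most closely. Over all groups the replicate letter showed no pairing. The median correlation of residuals was −0.000889 for libraries of different groups with the same letter and −0.000404 for other letters. Between the groups of a comparison the median for a letter ran from −0.0893 to 0.156. The highest was that of letter a for progenitor day 14 against day 0, so pairing limited to some groups is not excluded.

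RLE and DESeq2 factors of all 90 libraries moved the median log2 fold change of all genes. With RLE the shift was −0.11 for genotype in progenitors, 0.11 for progenitor day 14 against day 0, 0.18 for differentiated against progenitor, 0.26 for DMSO in thawed cells, −0.11 for thawed against fresh and 0.18 for the difference of the DMSO effect. With DESeq2 the shifts were −0.17, 0.13, 0.16, 0.27, −0.13 and 0.18 in the same order, and −0.13 for genotype in fresh cells. The share of calls that were higher moved with them, from 52.5% to 69.4% with RLE and 73.8% with DESeq2 for progenitor day 14, from 48.4% to 72.1% and 69.6% for differentiated against progenitor, and from 22.2% to 47.5% and 26.1% for DMSO in fresh cells. The factors of DESeq2 rested on 37 genes without a zero, and on 8875 genes when the nearly empty libraries were left out.

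The model was tested on simulated data, 8 sets of counts with 200 genes changed in each. For genotype in fresh cells, 23.3%, 45.5%, 79.3% and 95.5% of genes changed by 1.3, 1.5, 2 and 4 times were recovered, and 3.56% of calls were false. For DMSO in fresh cells the recovered shares were 5.75%, 21.0%, 50.5% and 82.5%, with 4.05% false calls. For thawed against fresh they were 52.8%, 73.8%, 95.0% and 97.8%, with 9.50% false calls, above the 5% aimed at. Simulated counts were drawn for each gene apart, without the component shared by libraries within groups. The shares therefore do not cover false or missed calls that go with that component.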

Results

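HepaRG is a human liver progenitor cell line that can mature in culture into hepatocyte-like and biliary-like cells. The series used BRB-seq, a method that counts the 3′ ends of transcripts from barcoded samples, to compare parental HepaRG cells with cells stably transduced by a lentivirus that carries CYP2D6. CYP2D6 is a cytochrome P450 enzyme that metabolises many drugs, and the series title names drug metabolism and toxicity testing in culture as the purpose. There were 15 conditions, each with 2 genotypes and 3 replicates per genotype, which gave 90 libraries. Progenitor cells were taken at days 0, 2, 4, 7 and 14, all without DMSO. Freshly differentiated cells and thawed cells were each taken at days 30 and 32 without DMSO and at days 32, 37 and 44 with DMSO, the solvent that drives and maintains differentiation of this line. Per the growth and treatment protocols, the cells of day 30 had already passed through 2 weeks with 1.7% DMSO, although their label reads no DMSO.

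The count table held 28307 genes, of which 12125 had enough counts to be tested. The total count of 87 libraries lay between 723391 and 3882866, with a median of 1935150. The other 3 libraries were nearly empty: parental progenitor day 2 replicate c held 212 counts, parental fresh day 30 replicate c held 505 and parental progenitor day 14 replicate c held 10137. Group means below, in counts scaled to a common library total (CPM), leave these 3 libraries out. In the 87 libraries a median of 16088 genes had a count, and the 10 most abundant genes of a library took between 7.74% and 24.1% of its counts. Replicates may be technical, since the labels do not say that a, b and c were separate cultures. Handling of molecular identifiers is not stated, so intervals and floors cover counting error only. Values are the mean ± SD of n libraries for CPM, and log2 fold change ± SE with the edgeR adjusted p over all genes tested. The SE was computed here as the size of the log2 fold change divided by the square root of the edgeR F statistic.

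CYP2D6 was higher in transduced than in parental cells at every status. In progenitors its level was 7.01 ± 3.22 CPM (n = 15) in transduced and 0.355 ± 0.504 CPM (n = 13) in parental cells, a log2 fold change of 4.24 ± 0.404 (18.9-fold, adjusted p = 3.3e-14). In fresh differentiated cells the levels were 10.1 ± 3.71 CPM (n = 15) and 0.882 ± 1.36 CPM (n = 14), a log2 fold change of 3.96 ± 0.386 (15.6-fold, adjusted p = 1.1e-13). Thawed cells had 11.4 ± 6.38 CPM (n = 15) and 0.590 ± 1.14 CPM (n = 15), a log2 fold change of 4.68 ± 0.387 (25.7-fold, adjusted p = 6.7e-18). Without replicate b of every group the log2 fold change of CYP2D6 was 4.82 in progenitors and 6.03 in thawed cells. The gene spans 42126499 to 42130810 on chromosome 22 of hg38 in the RefSeq gene table. The difference was called in each of the 15 conditions, with adjusted p between 1.3e-09 and 0.00159 over the 15 tests.

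A CYP2D6 count was present in all 15 transduced libraries of each status, and in 7 of 13 parental progenitor libraries, 8 of 14 parental fresh libraries and 5 of 15 parental thawed libraries. The lowest ratio of CYP2D6 between genotypes, 3.88 (95% interval 2.29 to 6.82), was in fresh cells at day 32 without DMSO, where the parental libraries held 20 CYP2D6 counts and the transduced libraries 56. Parental replicates b and c of that condition held 10 CYP2D6 counts each, and without these 2 libraries the log2 fold change of CYP2D6 in fresh cells was 5.02. The highest ratio among conditions with a parental count, 90.5 (95% interval 15.9 to 3607.02), was in thawed cells at day 30, with 1 parental CYP2D6 count and 104 transduced counts. Thawed parental cells at day 37 had no CYP2D6 count, and transduced CYP2D6 was at least 13.3-fold higher there, against a floor of 3 counts over the group. CYP2D6 was not called between conditions in any comparison over time, DMSO or thawing; at day 14 against day 0 of progenitors, for example, its log2 fold change was −0.17 ± 0.932 (edgeR, adjusted p = 0.957).

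Part of the signal over CYP2D6 cannot be assigned to a single gene. The pseudogene CYP2D7 lies beside CYP2D6 on chromosome 22, at 42139576 to 42144483, and is nearly identical to it in sequence. CYP2D7 stood at 2.26, 2.15 and 2.52 CPM in transduced progenitor, fresh and thawed cells, and at 0.341, 0.692 and 0.441 CPM in parental cells.

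**Figure D1:**
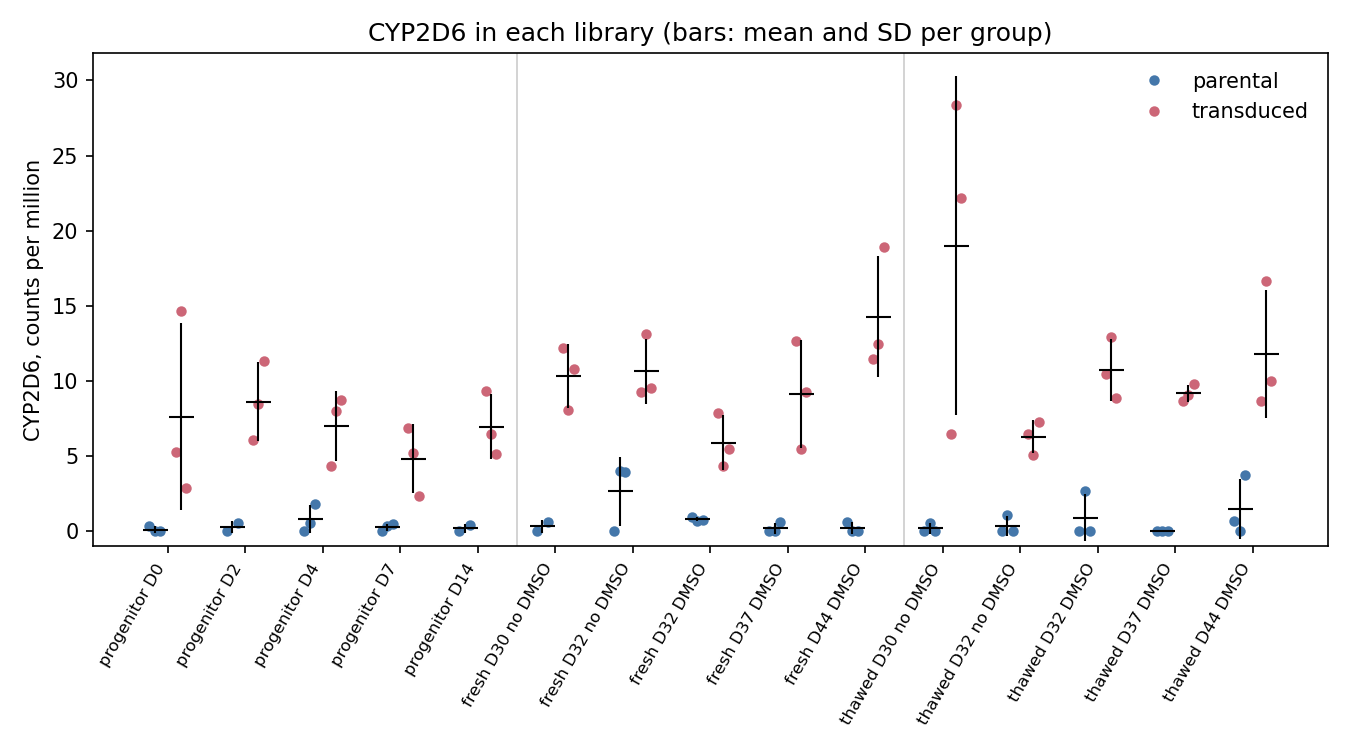
CYP2D6 in CPM (vertical axis) for each library of the 15 conditions (horizontal axis), parental in blue and transduced in red, with horizontal bars for the mean and vertical bars for the SD of usable replicates. The lowest transduced mean is 4.82 CPM, and the parental libraries of fresh cells at day 32 without DMSO include 2 at 4.00 and 3.97 CPM.

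In progenitors, several hepatocyte genes were slightly higher in the transduced line on average, with the clearest gap at days 0 and 7. The comparison asks what else differed between the genotypes before differentiation, averaged over the 5 days. SPINK1, a secreted trypsin inhibitor, stood at 1479.9 ± 1070.5 CPM (n = 15) in transduced and 793 ± 546 CPM (n = 13) in parental progenitors (log2 0.77 ± 0.0774, 1.71-fold, adjusted p = 2.0e-13). ASGR2, a subunit of the hepatocyte asialoglycoprotein receptor, rose 1.85-fold (log2 0.89 ± 0.116, adjusted p = 1.9e-08), from 22.3 ± 19.1 to 40.8 ± 31.2 CPM. The matricellular protein SPARC rose 1.69-fold (adjusted p = 8.9e-07) and the secreted phosphoprotein SPP1 rose 1.66-fold (adjusted p = 3.7e-06). IGFBP4, which binds insulin-like growth factors, was lower (log2 −0.59 ± 0.0939, adjusted p = 8.5e-06), from 197 ± 97.2 to 126 ± 47.5 CPM. In all, 132 genes were higher and 39 lower in transduced progenitors, a total of 171, of which 11 and 1 changed beyond 2-fold.

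Of the gene lists, phase II conjugation, which covers the enzymes that attach glucuronide, sulfate or glutathione to drugs, stood higher in transduced progenitors. Of its 31 tested members 5 rose and 0 fell (10 and 0 when adjusted over the list alone), with an adjusted p of 1.8e-07 from camera. Inflammation and acute phase genes were also higher, with 6 of 27 members up (11 when adjusted over the list alone, adjusted p = 4.0e-10). Among them the plasma glycoproteins ORM1 and ORM2 rose 1.44-fold and 1.37-fold. Hepatocyte secreted proteins had 8 of 37 members up (11 up and 1 down when adjusted over the list alone), including APOH at 1.44-fold, and the list was called at 6.2e-11, with an adjusted p of 0.111 with an estimated correlation. NRF2 targets, the antioxidant genes of that transcription factor, had 2 members up (adjusted p = 0.00561, and 0.203 with an estimated correlation). Ribosomal protein genes were called higher as a list (adjusted p = 7.0e-28, and 0.111 with an estimated correlation) with 0 of 39 members called (12 when adjusted over the list alone). Cell cycle genes were lower (1 of 37 down, 2 when adjusted over the list alone, adjusted p = 0.0311, and 0.361 with an estimated correlation). By day, the mean log2 level of the secreted proteins differed between transduced and parental progenitors by 0.45 at day 0, −0.068 at day 2, 0.021 at day 4, 0.61 at day 7 and −0.042 at day 14. For other P450 enzymes the differences were 0.20, −0.14, −0.10, 0.29 and −0.27 on the same days. At day 14 the parental SD was 0.494 for secreted proteins and 0.542 for other P450 enzymes, over 2 libraries. Replicate a, which stood apart from the other libraries of that day, was 1 of them, so the day 14 gaps depend on it. The calls of APOH, ORM1 and ORM2 ended without replicate a of every group and without replicate b, and that of IGFBP4 without replicate a. The count of 171 was 36 when only the progenitor libraries were fitted, 286 with RLE scaling and 26 with DESeq2. The majority turned with RLE: 77.2% of calls were higher with TMM, 21.3% with RLE and 61.5% with DESeq2, and 74.1% with RLE when the nearly empty libraries were left out.

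In fresh differentiated cells, hepatocyte genes were lower in the transduced line. SULT2A1, a sulfotransferase for steroids and bile acids, fell 1.57-fold (log2 −0.65 ± 0.0763, adjusted p = 5.4e-10), from 594 ± 210 CPM (n = 14) in parental to 374 ± 117 CPM (n = 15) in transduced cells. HPX, the haem-binding plasma protein hemopexin, fell 1.53-fold (log2 −0.62 ± 0.0841, adjusted p = 1.6e-07), from 1696 ± 857 to 1077 ± 503 CPM. The HLA class II chain HLA-DRA fell 1.74-fold (adjusted p = 7.9e-06), AGXT, which detoxifies glyoxylate, fell 1.64-fold (adjusted p = 0.000115), and SERPINC1, the gene of antithrombin, fell 1.44-fold (adjusted p = 1.2e-06). The chemokine gene CCL2 rose 1.76-fold (log2 0.81 ± 0.162, adjusted p = 0.000446) and SPINK1 rose 1.52-fold (log2 0.60 ± 0.0755, adjusted p = 5.2e-09). In total 183 genes were higher and 211 lower, of which 27 and 4 beyond 2-fold.

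Of the 22 tested P450 enzymes other than CYP2D6, 7 fell and 0 rose in transduced fresh cells (8 down when adjusted over the list alone, adjusted p = 2.3e-10). Hepatocyte secreted proteins had 14 of 37 members down (23 when adjusted over the list alone, adjusted p = 8.0e-24). Of 25 genes of sterol synthesis, 11 fell (16 when adjusted over the list alone, adjusted p = 2.1e-14), among them INSIG1, a sterol sensor, at 1.35-fold lower (adjusted p = 0.000464). The list of urea cycle, amino acid and glucose metabolism had 10 of 24 members down (11 when adjusted over the list alone, adjusted p = 2.6e-14). Hepatic transporters had 5 of 19 down (10 when adjusted over the list alone, adjusted p = 9.0e-08), bile acid synthesis 4 of 16 (8 when adjusted over the list alone, adjusted p = 1.2e-07) and fatty acid oxidation 5 of 23 (10 when adjusted over the list alone, adjusted p = 2.3e-09). Liver transcription factors were lower as a list with 1 of 21 members down (adjusted p = 0.00132). Cell cycle genes stood higher, with 2 of 37 up (8 when adjusted over the list alone, adjusted p = 9.3e-09). Phase II conjugation had 2 up and 6 down (3 and 9 when adjusted over the list alone) and was lower as a list at 0.000236, with an adjusted p of 0.0649 with an estimated correlation. Other calls that ended with an estimated correlation were acute phase genes (lower, adjusted p = 0.213 with an estimated correlation), lipid synthesis (lower, adjusted p = 0.0832 with an estimated correlation) and ribosomal protein genes (higher, 0 members called, adjusted p = 0.122 with an estimated correlation). The count of 394 was 637 with RLE scaling, 225 with DESeq2 and 606 with the score of the within-group component as a covariate. Of the calls, 46.4% were higher with TMM, 19.3% with RLE and 10.2% with DESeq2, and 43.8% with RLE when the nearly empty libraries were left out.

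Thawed cells showed lower hepatocyte genes in the transduced line as well, on average and with a smaller gap at day 32. NR1I3, the nuclear receptor CAR that senses foreign compounds, fell 2.04-fold (log2 −1.03 ± 0.177, adjusted p = 2.6e-05), from a mean of 27.5 CPM in parental to 13.8 CPM in transduced cells (n = 15 each). The alcohol dehydrogenase ADH1A fell 1.68-fold (log2 −0.75 ± 0.110, adjusted p = 4.2e-07) and ADH4 fell 1.58-fold (log2 −0.66 ± 0.0915, adjusted p = 9.3e-08). HPX fell 1.53-fold (log2 −0.62 ± 0.0832, adjusted p = 5.4e-08), from 1387 ± 699.9 to 858 ± 357 CPM. The secreted hepatokine FGL1 fell 1.55-fold (adjusted p = 1.5e-08), and SPINK1 rose 1.44-fold (log2 0.52 ± 0.0738, adjusted p = 1.5e-07). There were 96 genes higher and 163 lower, of which 22 and 3 beyond 2-fold.

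In transduced thawed cells, hepatocyte secreted proteins had 17 of 37 members down (2 up and 27 down when adjusted over the list alone, adjusted p = 4.7e-34). Urea cycle, amino acid and glucose metabolism had 9 of 24 down (2 up and 14 down when adjusted over the list alone, adjusted p = 3.9e-18). Sterol synthesis had 4 of 25 down (11 when adjusted over the list alone, adjusted p = 8.6e-13), including DHCR7, the enzyme of the final step of cholesterol synthesis, at 1.42-fold lower (adjusted p = 6.3e-06). Of the other P450 enzymes 7 of 22 fell (10 when adjusted over the list alone, adjusted p = 3.6e-09), and of phase II enzymes 5 of 31 fell (2 up and 8 down when adjusted over the list alone, adjusted p = 1.5e-08). Transporters had 5 down (7 when adjusted over the list alone, adjusted p = 1.2e-06), fatty acid oxidation 3 (6 when adjusted over the list alone, adjusted p = 5.4e-09) and bile acid synthesis 3 (1 up and 4 down when adjusted over the list alone, adjusted p = 0.000112). Acute phase genes had 4 of 27 down (adjusted p = 1.0e-06), lipid synthesis 2 of 18 (adjusted p = 0.00155) and liver transcription factors 1 of 21 (adjusted p = 3.2e-05). Cell cycle genes (adjusted p = 0.00166) and ribosomal protein genes (adjusted p = 4.9e-10) were higher as lists with 0 members called, and their adjusted p were 0.104 and 0.210 with an estimated correlation. By condition (days 30 and 32 without DMSO, then 32, 37 and 44 with DMSO), the genotype gap of the secreted proteins in thawed cells was −0.30, −0.18, −0.047, −0.40 and −0.45, and that of other P450 enzymes −0.34, −0.00094, −0.041, −0.44 and −0.45. In fresh cells the same gaps were −0.40, −0.26, −0.091, −0.25 and −0.49 for secreted proteins and −0.44, −0.18, −0.26, −0.27 and −0.27 for other P450 enzymes. Of the genotype calls in fresh and thawed cells, 50 were higher in both where 1.45 would be shared by chance, 113 were lower in both where 2.84 would be shared by chance, and 0 went opposite ways. The count of 259 was 472 with RLE scaling, 157 with DESeq2, 425 with the component score as a covariate and 480 when only thawed libraries were fitted, and the share of higher calls was 37.1% with TMM, 21.8% with RLE and 15.9% with DESeq2. The call of SPINK1 in thawed cells ended without replicate a.

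The genotype difference itself differed between fresh cells and progenitors in 165 genes, of which 148 had a lower value in fresh cells. AFM, a plasma protein that carries vitamin E, had a log2 genotype difference of 1.73 in progenitors and −0.67 in fresh cells (difference −2.40 ± 0.390, adjusted p = 1.8e-05). UGT2B15, a glucuronosyltransferase, went from 0.64 in progenitors to −0.51 in fresh cells (difference −1.16 ± 0.212, adjusted p = 0.000106), and CFHR2, a complement-related plasma protein, from 0.77 to −0.40 (difference −1.17 ± 0.258, adjusted p = 0.00277). Hepatocyte secreted proteins had 17 of 37 members with a lower genotype difference in fresh cells (23 when adjusted over the list alone), with a median of −0.55 (adjusted p = 1.9e-37). Medians were −0.36 for phase II conjugation, −0.28 for acute phase genes, −0.40 for urea cycle, amino acid and glucose metabolism, −0.29 for fatty acid oxidation, −0.27 for bile acid synthesis and −0.25 for sterol synthesis, and 0.46 for cell cycle genes. Each of these 8 lists was called with the preset and with an estimated correlation. The lists of other P450 enzymes, NRF2 targets, biliary and progenitor markers and p53 targets were called with the preset correlation only, with adjusted p of 0.0929, 0.0585, 0.107 and 0.107 with an estimated correlation. The call of UGT2B15 ended without replicate a and without replicate b, and that of CFHR2 also with DESeq2, which called 73 genes in place of 165.

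Between thawed and fresh cells, edgeR called 0 genes and camera 0 lists for a difference in the genotype effect. At an unadjusted p under 0.05 there were 510 such genes, and DESeq2 also called 0. The lowest adjusted p of a list was 0.0739, for cell cycle genes. Of the genotype calls, 17 were higher and 2 lower in both progenitors and fresh cells (1.99 and 0.679 by chance), and 25 went opposite ways. For progenitors and thawed cells the counts were 16 higher and 2 lower (1.05 and 0.524 by chance), with 26 opposite.

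Between day 0 and day 14 in culture, progenitors gained hepatocyte transcripts, after a fall below the start at days 2 and 4. The mean log2 level of the secreted proteins in parental cells was −1.55, −2.85, −2.61, −1.66 and 0.37 at days 0, 2, 4, 7 and 14. In transduced cells it was −1.09, −2.92, −2.59, −1.05 and 0.32. APOA2, an apolipoprotein of high-density lipoprotein, rose 20.9-fold (log2 4.38 ± 0.186, adjusted p = 4.1e-41), to 171 ± 50.5 CPM (n = 5) at day 14. APOA1 rose 9.87-fold (log2 3.30 ± 0.181, adjusted p = 3.4e-25), SERPINC1 9.34-fold and HPX 7.69-fold. CYP2C8, a drug-metabolising P450, rose 4.71-fold (log2 2.23 ± 0.165, adjusted p = 5.3e-22), and CYP3A4, the P450 that handles the largest share of drugs, rose 6.58-fold (log2 2.72 ± 0.259, adjusted p = 4.1e-13). The immediate-early transcription factors FOSB and FOS fell 27.7-fold (log2 −4.79 ± 0.497, adjusted p = 8.4e-12) and 24.0-fold (log2 −4.59 ± 0.335, adjusted p = 7.7e-18), and EDN1, the gene of the vasoconstrictor endothelin-1, fell 9.20-fold (adjusted p = 8.7e-16). In total 691 genes rose and 626 fell, of which 412 and 266 beyond 2-fold.

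At day 14 of progenitors, 34 of 37 hepatocyte secreted proteins rose and 0 fell (35 and 0 when adjusted over the list alone, adjusted p = 2.4e-123). Other P450 enzymes had 15 of 22 up and 1 down (19 and 1 when adjusted over the list alone, adjusted p = 2.7e-19), and urea cycle, amino acid and glucose metabolism had 15 of 24 up (16 when adjusted over the list alone, adjusted p = 2.6e-26). Phase II enzymes had 13 up and 1 down (17 and 2 when adjusted over the list alone, adjusted p = 1.9e-13), transporters 8 up (10 when adjusted over the list alone, adjusted p = 2.5e-08), bile acid synthesis 9 up (11 when adjusted over the list alone, adjusted p = 7.0e-08) and fatty acid oxidation 8 up and 1 down (14 and 2 when adjusted over the list alone, adjusted p = 4.3e-10). Cell cycle genes fell, 14 of 37 (22 when adjusted over the list alone, adjusted p = 7.0e-08). Of 24 mesenchymal and matrix genes 10 fell and 1 rose (11 and 1 when adjusted over the list alone, adjusted p = 1.3e-09), and of 21 p53 targets 11 fell (12 when adjusted over the list alone, adjusted p = 7.1e-10). The unfolded protein and amino acid stress list had 6 of 26 down (10 when adjusted over the list alone, adjusted p = 0.000352), and NRF2 targets had 7 of 24 down and 1 up (10 and 3 when adjusted over the list alone, adjusted p = 0.000302). Biliary and progenitor markers (2 up and 5 down of 13), the stellate, fibroblast and endothelial markers (2 down of 5) and the macrophage and leukocyte markers (2 up of 4) were each called at 0.0438, with adjusted p of 0.0892, 0.0569 and 0.0558 with an estimated correlation. Ribosomal protein genes had 14 of 39 down (adjusted p = 3.4e-15, and 0.122 with an estimated correlation). Acute phase genes had 11 up and 9 down and were not called (adjusted p = 0.0539), and their median of −0.06 and the test's direction, higher, differed in sign. Parental replicate a of day 14 stood apart from the other 4 libraries of that day. In CPM without TMM factors it had 822 of CYP3A4 against 90.5 to 118, 48.2 of FOS against 1.92 to 4.12 and 3504.6 of APOA1 against 1092.5 to 1576.1. Without that library the log2 fold changes were 1.90 for CYP3A4, −6.26 for FOS and −7.20 for FOSB, and 1146 genes were called in place of 1317.

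Fresh differentiated cells at day 44 with DMSO carried far more drug-metabolism transcripts than progenitors at day 14. CYP2E1, a P450 that oxidises ethanol and small solvents, was 24.9-fold higher (log2 4.64 ± 0.215, adjusted p = 4.0e-28), at 578 ± 139.8 CPM (n = 6) against 23.4 ± 27.0 CPM (n = 5). CYP3A4 was 10.6-fold higher (log2 3.40 ± 0.248, adjusted p = 1.1e-17), at 2719.5 ± 828 against 258 ± 322 CPM. The antioxidant enzyme GPX2 was 12.6-fold higher and the lipogenic regulator THRSP 10.6-fold. DKK1, a secreted inhibitor of Wnt signalling, was lower (log2 −2.59 ± 0.226, adjusted p = 5.8e-18), SPP1 5.83-fold lower (log2 −2.54 ± 0.172, adjusted p = 1.0e-24) and LUM, a matrix proteoglycan, 4.82-fold lower. In total 974 genes were higher and 1039 lower, of which 412 and 392 beyond 2-fold.

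In the differentiated cells, hepatocyte secreted proteins had 29 of 37 members up and 1 down (30 and 1 when adjusted over the list alone, adjusted p = 4.6e-51) and other P450 enzymes 15 of 22 up and 2 down (17 and 3 when adjusted over the list alone, adjusted p = 3.8e-28). Sterol synthesis had 16 of 25 up (19 when adjusted over the list alone, adjusted p = 9.6e-16), for example INSIG1 at 3.84-fold. Phase II enzymes had 17 of 31 up and 4 down (20 and 4 when adjusted over the list alone, adjusted p = 2.6e-10), transporters 11 of 19 up (12 up and 1 down when adjusted over the list alone, adjusted p = 4.6e-12) and urea cycle, amino acid and glucose metabolism 12 of 24 up and 1 down (15 and 2 when adjusted over the list alone, adjusted p = 3.4e-13). Lipid synthesis had 10 of 18 up and 1 down (11 and 1 when adjusted over the list alone, adjusted p = 1.2e-06), NRF2 targets 11 of 24 up and 2 down (14 and 3 when adjusted over the list alone, adjusted p = 8.1e-07), and the metallothioneins, small proteins that bind zinc and copper, 5 of 7 up and 1 down (adjusted p = 1.7e-06). The stress list of unfolded protein and amino acid genes had 10 of 26 up and 1 down (adjusted p = 0.00127), and liver transcription factors had 6 of 21 up (adjusted p = 0.00529). Biliary and progenitor markers had 3 of 13 down (6 when adjusted over the list alone, adjusted p = 0.000223), and stellate, fibroblast and endothelial markers 2 of 5 down (adjusted p = 0.000805). Lower calls that ended with an estimated correlation were the mesenchymal and matrix genes (7 down and 1 up, adjusted p = 0.0935 with an estimated correlation), heat shock (4 down and 1 up, 0.111), acute phase genes (11 down and 5 up, 0.315) and ribosomal protein genes (10 down, 0.319). The median and the test differed in sign for the uncalled foetal liver markers (median −0.32, test higher) and interferon genes (median −0.06, test higher). Without parental progenitor day 14 replicate a, the log2 fold changes were 5.66 for CYP2E1, 4.21 for CYP3A4 and 4.39 for GPX2, and 1896 genes were called in place of 2013. DESeq2 called 1237.

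**Figure D2:**
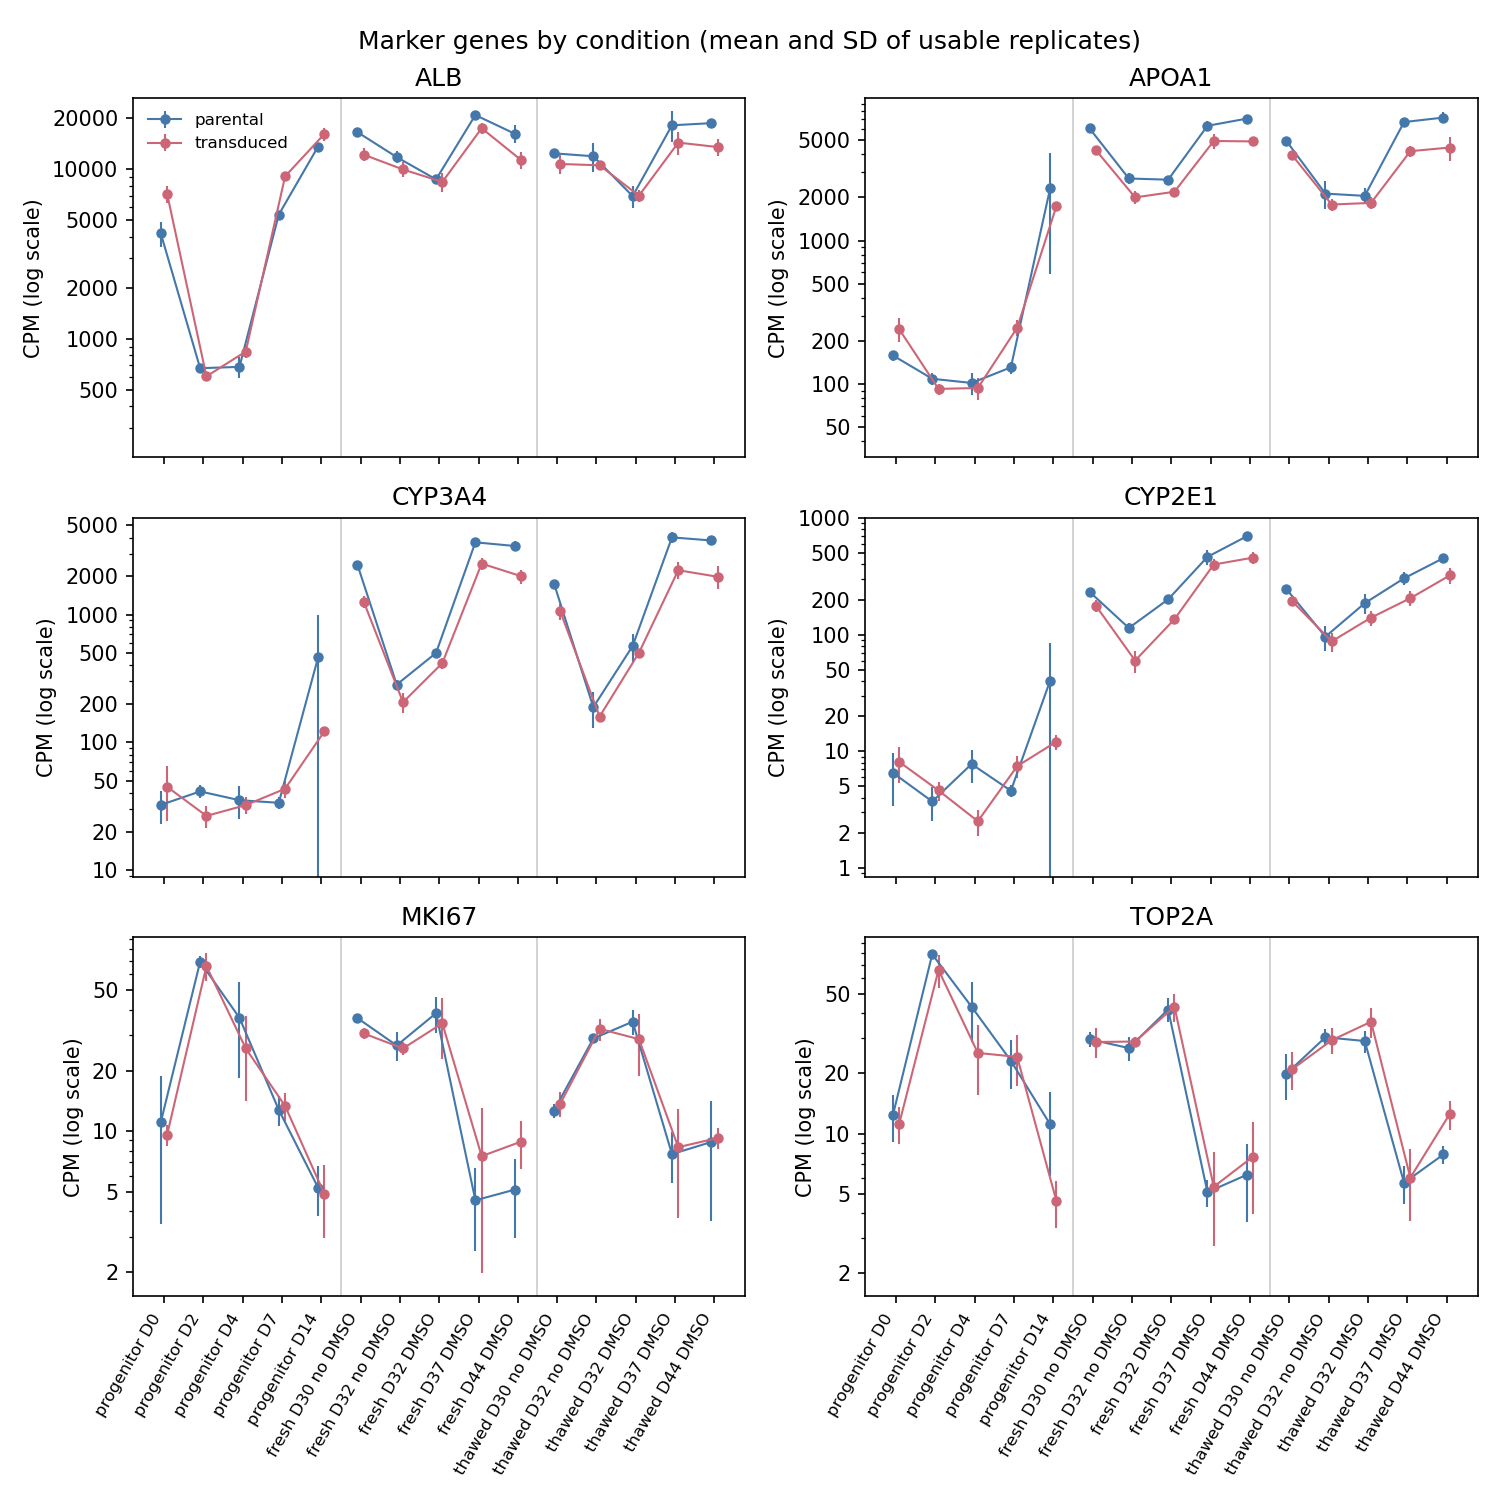
Level of 6 genes in CPM on a log axis (vertical) over the 15 conditions (horizontal) in parental and transduced cells, as the mean with SD of usable replicates, where SD bars that reach below 0 run to the bottom of the axis. ALB and APOA1 are secreted by hepatocytes, CYP3A4 and CYP2E1 are P450 enzymes, and MKI67 and TOP2A mark dividing cells. CYP3A4 is 2719.5 CPM on average in fresh cells at day 44 with DMSO.

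DMSO for 2 more days in fresh cells, day 32 with against without, lowered acute phase genes and raised metallothioneins. CRP, the acute phase marker C-reactive protein, fell 7.30-fold (log2 −2.87 ± 0.298, adjusted p = 5.5e-13), from 31.5 ± 7.09 CPM (n = 6) to 4.42 ± 2.50 CPM (n = 6). The retinol dehydrogenase RDH16 fell 4.72-fold (log2 −2.24 ± 0.177, adjusted p = 2.8e-19), and APCS, serum amyloid P component, fell 2.82-fold (adjusted p = 7.1e-18), from 666 ± 46.6 to 236 ± 36.7 CPM. CYP2E1 rose 1.98-fold (log2 0.99 ± 0.174, adjusted p = 8.6e-05), to 168 ± 38.1 CPM, and CYP3A4 rose 1.89-fold (log2 0.92 ± 0.222, adjusted p = 0.00967). There were 58 genes higher and 203 lower, of which 16 and 68 beyond 2-fold.

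Of 27 acute phase genes, 10 fell with DMSO in fresh cells (18 when adjusted over the list alone, adjusted p = 3.3e-22), including LBP, which binds bacterial lipopolysaccharide, at 1.98-fold lower and the cytokine IL32 at 1.76-fold lower. Metallothioneins had 3 of 7 up (5 up and 1 down when adjusted over the list alone, adjusted p = 2.5e-08), with MT1E at 1.67-fold. Sterol synthesis had 3 of 25 down (9 when adjusted over the list alone, adjusted p = 1.2e-06), with FDPS, which makes farnesyl diphosphate, 1.71-fold lower. Lists whose call ended with an estimated correlation were the hepatocyte secreted proteins (lower, 7 of 37 down, adjusted p = 0.130 with an estimated correlation), biliary and progenitor markers (lower, 0.0602), phase II conjugation (lower, 0.206), fatty acid oxidation (lower, 0.206), lipid synthesis (lower, 0.126), cell cycle (higher, 0.126), interferon response (higher, 0.0668) and ribosomal proteins (higher, 0.485). Other P450 enzymes, with 5 up and 3 down, had a median of −0.08 and a test in the other direction that was not called (adjusted p = 0.195). Without the 2 parental libraries that held 10 CYP2D6 counts each, 128 genes were called in place of 261, and the call of CYP3A4 ended, as it did without replicate c. DESeq2 called 88 genes, and the call of CYP2E1 ended without replicate c.

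DMSO for 2 more days in thawed cells lowered acute phase and secreted protein genes and raised CYP2B6 and CYP3A4. RDH16 fell 6.35-fold (log2 −2.67 ± 0.178, adjusted p = 5.0e-25), APCS 5.16-fold (log2 −2.37 ± 0.130, adjusted p = 2.2e-31) and LBP 4.09-fold (log2 −2.03 ± 0.126, adjusted p = 2.7e-27), the last from 412 ± 36.8 CPM (n = 6) to 101 ± 14.3 CPM (n = 6). CRP fell 13.4-fold, and NNMT, which methylates nicotinamide, fell 2.74-fold (adjusted p = 6.6e-17). CYP2B6, a P450 that is induced through CAR, rose 3.11-fold (log2 1.64 ± 0.317, adjusted p = 0.000208), and CYP3A4 rose 3.08-fold (log2 1.63 ± 0.225, adjusted p = 1.8e-07), from 174 ± 40.8 to 535 ± 97.9 CPM. There were 276 genes higher and 578 lower, of which 88 and 171 beyond 2-fold. Of the DMSO calls in fresh and thawed cells, 34 were higher in both where 1.32 would be shared by chance, 153 lower in both where 9.68 would be, and 0 opposite.

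Acute phase genes had 17 of 27 members down with DMSO in thawed cells (1 up and 20 down when adjusted over the list alone, adjusted p = 5.0e-40), and hepatocyte secreted proteins 18 of 37 down (22 when adjusted over the list alone, adjusted p = 1.9e-18), among them the fibrinogen gene FGB at 2.61-fold lower. Ribosomal protein genes had 19 of 39 down (31 when adjusted over the list alone, adjusted p = 1.2e-27, and 0.105 with an estimated correlation). Of urea cycle, amino acid and glucose genes 8 fell and 2 rose, of fatty acid oxidation genes 8 fell and 1 rose, of sterol genes 3 fell, and of biliary and progenitor markers 3 fell and 1 rose; each list was called lower with the preset correlation, with an adjusted p of 0.105 with an estimated correlation. Phase II conjugation (4 down, 0.135 with an estimated correlation), cell cycle (5 down, 0.320) and NRF2 targets (higher, 4 up and 1 down, 0.263) also lost their calls. The DMSO effect differed between thawed and fresh cells for 2 genes, LBP (difference −1.05 ± 0.173, adjusted p = 0.000233) and APCS (difference −0.87 ± 0.176, adjusted p = 0.0152). As lists, acute phase genes (median difference −0.47, adjusted p = 8.1e-13) and cell cycle genes (median difference −0.44, adjusted p = 8.2e-10) responded differently, and the secreted proteins, metallothioneins and ribosomal proteins did so with the preset correlation only (adjusted p = 0.187 with an estimated correlation for each). Both calls ended without the 2 parental libraries of fresh cells that held 10 CYP2D6 counts each, and DESeq2 called 0 genes. With RLE scaling 1705 genes were called for DMSO in thawed cells in place of 854, and with only the compared libraries 1422. The majority turned: 32.3% of calls were higher with TMM, 84.7% with RLE and 76.7% with DESeq2, and 29.2% with RLE when the nearly empty libraries were left out.

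From day 32 to day 44 with DMSO, fresh cells gained hepatocyte transcripts and lost cell cycle transcripts. Day 32 was a low point for the secreted proteins, so part of this gain was a return to the day 30 level. In parental cells they stood at 1.33 at day 30, 0.199 at day 32 with DMSO and 1.69 at day 44. In transduced cells they stood at 0.924, 0.108 and 1.205. ALB was no higher at day 44 than at day 30, at 16212 against 16558 CPM in parental and 11351 against 12195 CPM in transduced cells. THRSP rose 37.3-fold (log2 5.22 ± 0.372, adjusted p = 2.7e-23), and FABP1, the liver fatty acid binding protein, rose 9.28-fold (log2 3.21 ± 0.131, adjusted p = 7.0e-43), from 507 ± 98.3 CPM (n = 6) to 4763 ± 1166 CPM (n = 6). ARG1, the final enzyme of the urea cycle, rose 8.82-fold and CYP4F2, a fatty acid hydroxylase, 7.30-fold. CENPF, a kinetochore protein, fell 8.29-fold (log2 −3.05 ± 0.239, adjusted p = 2.1e-19), TOP2A fell 6.18-fold (log2 −2.63 ± 0.235, adjusted p = 2.2e-17) and MKI67, the Ki-67 proliferation marker, fell 5.29-fold (log2 −2.40 ± 0.261, adjusted p = 3.6e-13). There were 804 genes higher and 638 lower, of which 385 and 316 beyond 2-fold.

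In fresh cells over these days, 33 of 37 cell cycle genes fell (36 when adjusted over the list alone, adjusted p = 1.2e-54) and 34 of 37 secreted proteins rose (37 when adjusted over the list alone, adjusted p = 3.3e-80). The list of urea cycle, amino acid and glucose metabolism had 18 of 24 up (20 up and 1 down when adjusted over the list alone, adjusted p = 2.3e-33), sterol synthesis 18 of 25 (22 when adjusted over the list alone, adjusted p = 1.6e-25), phase II 20 of 31 (21 up and 1 down when adjusted over the list alone, adjusted p = 2.0e-14) and other P450 enzymes 14 up and 1 down of 22 (15 and 2 when adjusted over the list alone, adjusted p = 8.3e-22). Transporters had 12 of 19 up (14 when adjusted over the list alone, adjusted p = 8.0e-13), bile acid synthesis 10 of 16 (11 when adjusted over the list alone, adjusted p = 7.3e-11), lipid synthesis 10 up and 1 down of 18 (12 and 1 when adjusted over the list alone, adjusted p = 7.3e-14), fatty acid oxidation 12 up and 1 down of 23 and acute phase genes 13 up and 2 down of 27 (adjusted p = 7.3e-11). Interferon response genes had 3 of 33 down (adjusted p = 0.0276). Liver transcription factors (higher, 5 up, adjusted p = 0.0538 with an estimated correlation) and ribosomal proteins (lower, 1 down, 0.558) lost their calls. Biliary and progenitor markers, not called, had a median of 0.07 and a test in the other direction.

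Thawed cells over the same days also gained hepatocyte transcripts and lost cell cycle transcripts. Here too day 32 was a low point. The secreted proteins stood at 0.96 at day 30, −0.14 at day 32 with DMSO and 1.49 at day 44 in parental cells. In transduced cells they stood at 0.65, −0.19 and 1.04. SPP2, a secreted liver phosphoprotein, rose 20.8-fold (log2 4.38, adjusted p = 6.7e-31), ARG1 12.7-fold (log2 3.67 ± 0.293, adjusted p = 6.6e-17), the organic anion transporter SLC22A7 10.2-fold and SERPIND1, heparin cofactor II, 8.83-fold (adjusted p = 8.1e-37). The aldehyde dehydrogenase ALDH3A1 fell 7.54-fold (log2 −2.92 ± 0.151, adjusted p = 7.0e-34), from 211 ± 24.0 CPM (n = 6) to 28.2 ± 7.56 CPM (n = 6), the mitotic regulator CDC20 4.91-fold and cyclin B1, CCNB1, 4.08-fold. There were 694 genes higher and 486 lower, of which 358 and 218 beyond 2-fold. Calls over time in fresh and thawed cells shared 453 higher genes (46.0 by chance) and 235 lower genes (25.6 by chance), with 2 opposite.

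In thawed cells 35 of 37 secreted proteins rose (35 when adjusted over the list alone, adjusted p = 7.0e-111) and 28 of 37 cell cycle genes fell (32 when adjusted over the list alone, adjusted p = 1.3e-39). Urea cycle, amino acid and glucose metabolism had 18 of 24 up (20 when adjusted over the list alone, adjusted p = 7.1e-40) and acute phase genes 16 up and 1 down of 27 (20 and 1 when adjusted over the list alone, adjusted p = 1.1e-25), including complement C3 at 3.27-fold. Other P450 enzymes (16 up and 3 down), phase II (17 up), transporters (12 up), sterol synthesis (12 up), bile acid synthesis (7 up), fatty acid oxidation (13 up), lipid synthesis (11 up and 1 down) and liver transcription factors (6 up and 1 down) were also called higher, and p53 targets (5 down) lower, with either correlation. Mesenchymal and matrix genes (5 up and 1 down, adjusted p = 0.0581 with an estimated correlation) and NRF2 targets (3 down and 1 up, 0.301) lost their calls. DESeq2 called 851 genes in fresh and 706 in thawed cells in place of 1442 and 1180. Without replicate c the log2 fold change of SPP2 was 5.00.

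**Figure D3:**
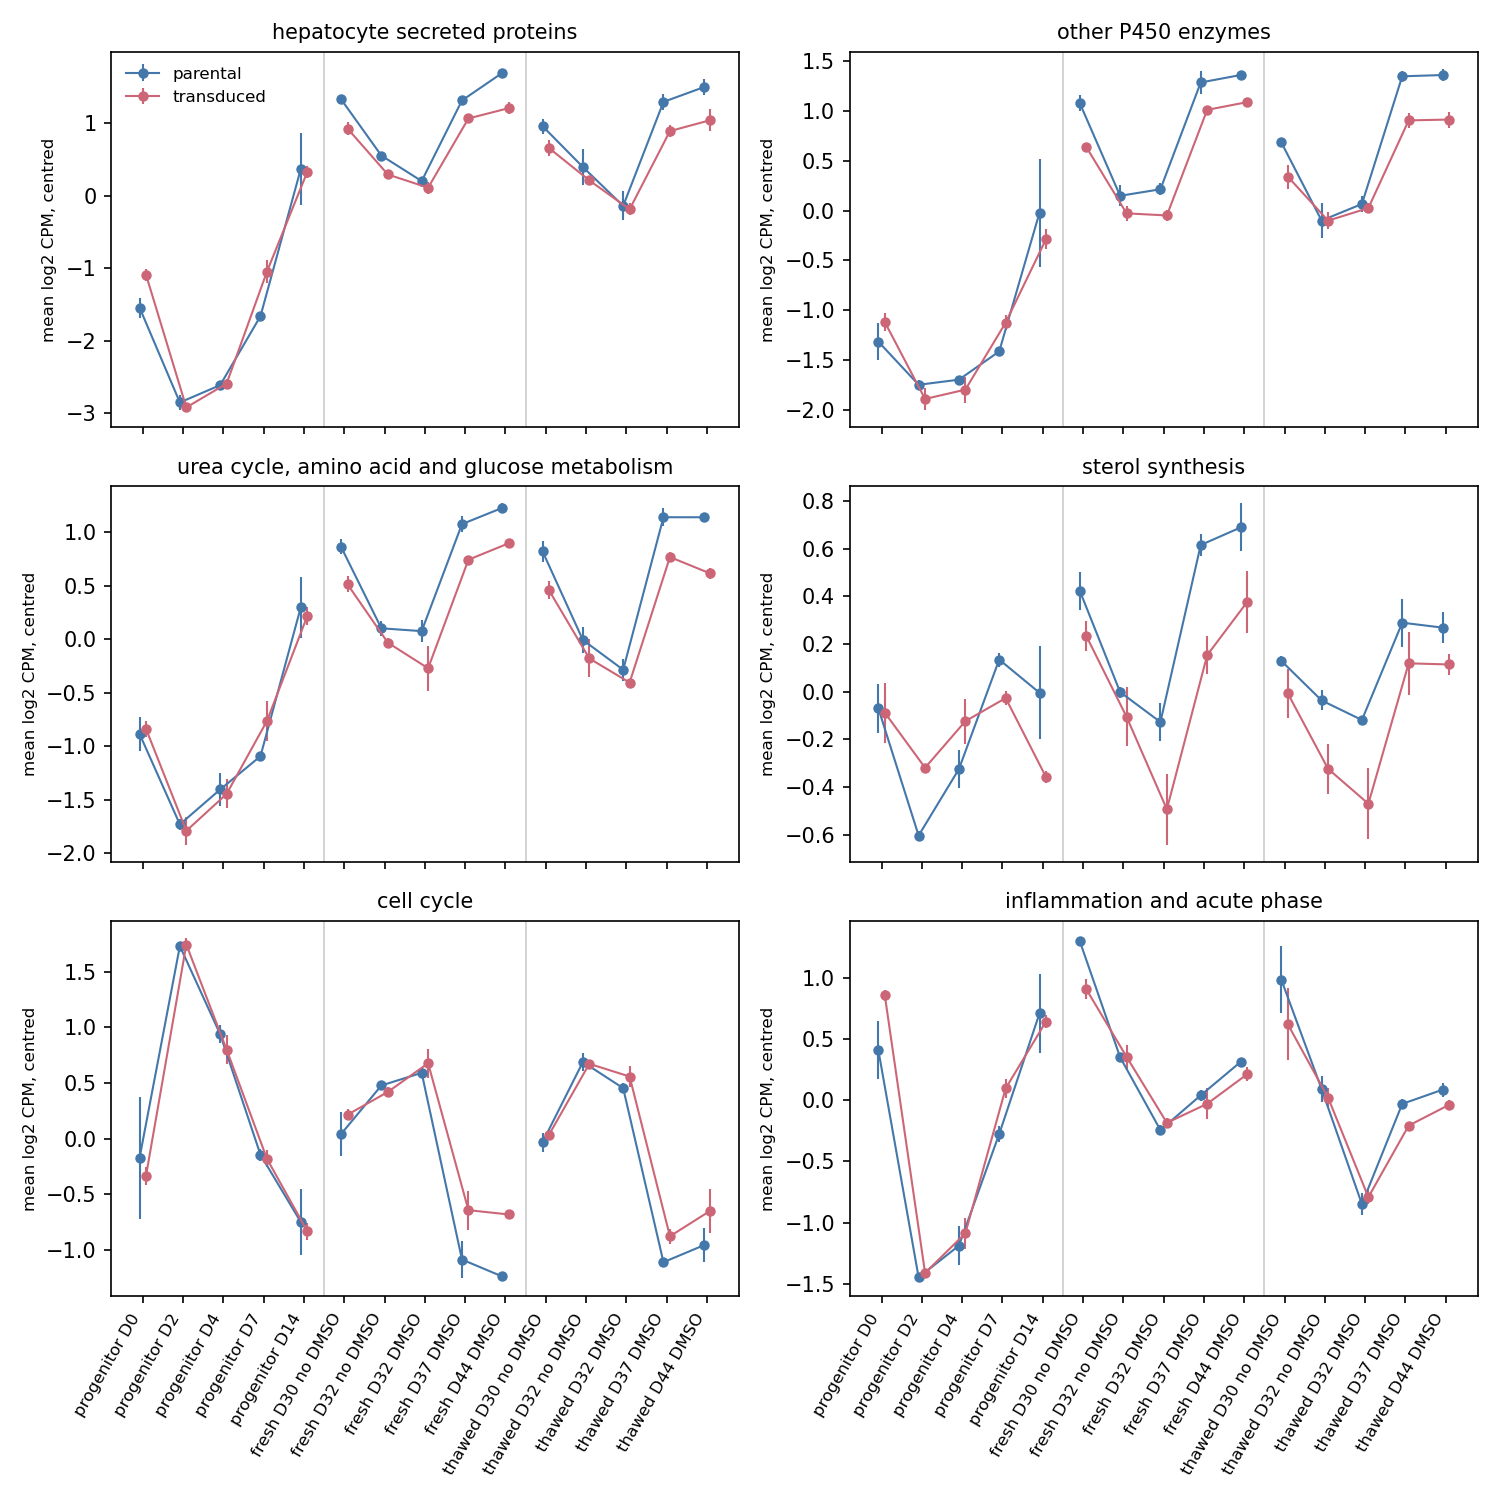
Mean of the centred log2 CPM of the tested members of 6 gene lists (vertical axis) over the 15 conditions (horizontal axis) in parental and transduced cells, as the mean with SD of usable replicates. Secreted proteins, P450 enzymes and the metabolic list rise from day 32 to day 44 with DMSO as cell cycle genes fall, with the transduced mean below the parental mean at days 37 and 44 for the first 4 lists.

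Thawed cells, averaged over the 5 matched conditions and both genotypes, differed from fresh cells by small amounts in many genes. CALR, the chaperone calreticulin, was 1.85-fold lower (log2 −0.89 ± 0.138, adjusted p = 1.5e-05), at 926 ± 367 CPM (n = 30) against 1873 ± 1095 CPM (n = 29). The copper-carrying plasma protein CP was 1.61-fold lower (log2 −0.69 ± 0.105, adjusted p = 1.2e-05), the complement component C5 also lower (log2 −0.59 ± 0.0889, adjusted p = 2.8e-06) and FGL1 1.31-fold lower (adjusted p = 2.8e-06). SNHG17, a host gene of small nucleolar RNAs, was 1.34-fold higher (log2 0.42 ± 0.0597, adjusted p = 3.7e-07) and the protease inhibitor CSTA 1.29-fold higher (adjusted p = 5.6e-06). There were 786 genes higher and 742 lower, of which 3 and 12 beyond 2-fold. This balance depends on the scaling: 51.4% of calls were higher with TMM, 11.04% with RLE and 2.495% with DESeq2, and 52.2% and 49.3% with RLE and DESeq2 when the nearly empty libraries were left out.

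Acute phase genes had 16 of 27 members down in thawed cells (18 when adjusted over the list alone, adjusted p = 2.3e-16), secreted proteins 19 of 37 (20 when adjusted over the list alone, adjusted p = 2.2e-12) and ribosomal proteins 32 up and 1 down of 39 (38 and 1 when adjusted over the list alone, adjusted p = 9.4e-33). Sterol synthesis had 8 of 25 down (1 up and 11 down when adjusted over the list alone, adjusted p = 0.000102), transporters 5 of 19 (adjusted p = 0.000392) and mesenchymal and matrix genes 6 of 24 (adjusted p = 0.000486), while heat shock genes had 4 of 15 up (adjusted p = 0.00471). Lower lists whose call ended with an estimated correlation were the other P450 enzymes (2 down, adjusted p = 0.0580 with an estimated correlation), lipid synthesis (5 down and 1 up, 0.0580), interferon response (4 down and 1 up, 0.0580), liver transcription factors (4 down, 0.0571), urea cycle, amino acid and glucose metabolism (3 down, 0.238) and bile acid synthesis (4 down, 0.116). Phase II conjugation, with 5 up and 2 down, had a median of −0.07 and a test in the other direction that was not called (adjusted p = 0.396). Within groups, a shared set of genes separated the replicates and took 10.2% of the variance between them; its score was lower in thawed than in fresh cells by 0.634 log2 units and in 9 of 10 matched pairs. With that score as a covariate 688 of the 1528 calls held, the log2 fold change of CALR was −0.45 ± 0.0659, that of CP −0.75, and that of the sterol enzyme HMGCS1 moved from −0.94 to −0.27. The count of 1528 was 209 without replicate a and 464 without replicate b. In simulated data, which held no such shared set of genes, 9.50% of the calls of this comparison were false.

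Of the fixed lists, the 6 tested foetal liver markers were called in none of the 13 comparisons made with camera, and their lowest adjusted p was 0.0836, for genotype in thawed cells. The mitochondrially encoded transcripts could not be tested, since 0 of the 31 symbols searched were in the count table. Over the 13 comparisons camera made 147 list calls with the preset correlation, and 96 of them held with an estimated correlation.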

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

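The tests of the 3 patterns below were chosen only after the result was seen, and the tests by other splits of the libraries were planned.

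The effect of genotype differed between fresh cells and progenitors for 165 genes, by a test of the difference itself. The differences in log2 were −2.40 for AFM, −1.19 for the alcohol dehydrogenase ADH1A, −1.18 for ADH1C, −1.17 for CFHR2 and −1.16 for UGT2B15. The calls of ADH1A and ADH1C ended under 8 and 9 of the alternatives, and their differences were −1.94 without replicate a and −2.13 without replicate b. By the same kind of test, 8 gene lists differed: median differences were −0.55 for hepatocyte secreted proteins, −0.36 for phase II conjugation, −0.28 for acute phase genes, −0.27 for bile acid synthesis, −0.25 for sterol synthesis, −0.40 for urea cycle, amino acid and glucose metabolism, −0.29 for fatty acid oxidation and 0.46 for cell cycle genes. The effect of DMSO differed between thawed and fresh cells for 2 genes, LBP at −1.05 and APCS at −0.87, and for 2 lists, cell cycle genes with a median of −0.44 and acute phase genes with −0.47.

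Of 100 splits of the compared usable libraries within conditions, the real one included, 1 gave as many calls as the real split for genotype in fresh cells (680 real, 5 the highest other), genotype in thawed cells (480 and 32), progenitor day 14 against day 0 (787 and 520), differentiated against progenitor (2111 and 1045), DMSO in fresh cells (370.0 and 281), DMSO in thawed cells (1422 and 152), day 44 against day 32 in fresh cells (1438 and 378) and in thawed cells (1393 and 513) and thawed against fresh (1844 and 121). For these counts the values argue against chance in the assignment of libraries. A share of 1 of 100 is the lowest that these splits can give, and it was not adjusted over the comparisons. The splits cannot exclude chance among separate cultures, since replicates may be technical. For genotype in progenitors 3 splits gave as many (53 and 241), for the difference of genotype effects between fresh cells and progenitors 2 (167 and 838) and for the difference of DMSO effects 4 (31 and 485). Chance is not excluded there, since these shares of splits were not adjusted over the comparisons and other splits call several times the real count. Such splits point to a structure of the samples. The splits with 241 and 838 calls had the largest differences in the component score of the other splits, 1.06 and −1.86 log2 units against −0.10 and 0.22 in the real splits. The split with 281 calls for DMSO in fresh cells also had the largest difference of its other splits, −1.17. The split with 485 calls had −0.70 against 0.17 in the real split, and 26 other splits had larger differences, up to 1.65. The size of the score difference alone therefore does not account for its calls. That split was not fitted with the score as a covariate, and no other structure was tested. For the difference of genotype effects between thawed and fresh cells the real split called 0 genes, so 100 of 100 splits had to give as many (the highest other gave 3), and the count says nothing about chance.

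Replicates of the same group differed on a shared set of genes, whose score ran from 5.26 to 8.12 log2 units, and of 1528 calls in thawed against fresh 840 did not hold with the score as a covariate. The tables argue against depth, since the score and the log2 total count had r = 0.128 within groups (permutation p = 0.234; rho = 0.141, permutation p = 0.192; r = 0.202 without the 2 libraries farthest from the median). A candidate explanation is priming at stretches that pair with runs of T: 66.2% of 334 component genes had a run of 10 T near the transcript end. From genes of like expression 12.8% was expected. Against background genes of any expression (684 of 6235), Fisher's exact test, with genes taken as independent, gave p = 3.1e-116. Runs of A, at 1.36 times the expected share, stay open. Inside groups lay 42.1% of the score's variance. With libraries ordered by condition, then parental before transduced, then by letter, the score rose and fell in a regular cycle. Libraries at a fixed low point scored 5.34 to 5.79 and those at a fixed high point 6.89 to 7.78, across status, genotype and DMSO. Both points were picked from these same scores. At the places just before the low point, scores were 5.26 to 6.09 except in fresh cells at day 32. There they were 7.15, 6.71 and 6.35 without DMSO (parental) and 7.54 (parental), 7.17 and 6.95 (transduced) with DMSO. The cycle argues against the state of the cells as the only source of the score. What the order stands for was not tested. An uneven spread of the component between thawed and fresh libraries cannot be told apart from thawing, since over all 1528 calls a median of 75.02% of the log2 value was left with the score as a covariate (SE over genes 0.917%; median size 0.283 before and 0.189 after), between none and all of it. The 840 calls ended as their median fell from 0.337 to 0.151 with an SE of 0.103 and then 0.0786. The score itself was lower in thawed cells in 9 of 10 matched pairs. The exact sign-flip test (p = 0.00781) takes the pairs as independent, which the cycle in library order makes uncertain.

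Across genes called over time, the genotype effect followed the change from day 0 to day 14 in progenitors (r = 0.390 across genes, highest other split 0.339) and opposed the change from day 32 to day 44 in fresh cells (r = −0.603, 0.525) and thawed cells (r = −0.610, 0.539). Genes are not independent replicates; 1 of 100 splits gave as large an r in each case, and the secreted proteins stood lower in transduced cells in 5 of 5 fresh and 5 of 5 thawed conditions (by as little as −0.047, less than the SD of 0.199 of parental replicates) but higher on only 3 of 5 days in progenitors (0.45 at day 0, 0.61 at day 7, 0.021 at day 4). At day 14 of progenitors the parental mean rests on 2 libraries with an SD of 0.494, 1 of them replicate a, which stood apart. An uneven spread of the library component is argued against in fresh and in thawed cells. In both, 100% of the genes called lower in transduced cells held with the score as a covariate. A smaller share of hepatocyte-like cells stays open: biliary and progenitor markers had a median log2 of −0.049 (SE 0.0430, 13 genes) in fresh and −0.13 (SE 0.113) in thawed cells. Whether transduced progenitors stood further along stays open, and a hypothesis is that transduced cultures stood less far along after differentiation, which may belong to CYP2D6 or to the separate history of the transduced line, since the design has only 1 transduced line and the difference between these was not tested.

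Parental replicates b and c of fresh cells at day 32 without DMSO held 10 CYP2D6 counts each, 4.00 and 3.97 CPM, while replicate a held 0. A mix with RNA or reads of transduced cells may account for this, since over 257 genes called for genotype in thawed cells the 2 libraries lay at a mean position of 0.219 (SE 0.0901) between parental replicate a and the transduced libraries, below the share of 0.352 that the CYP2D6 counts would need, although the position was only 0.0700 over genes called in fresh cells, a choice that uses the 2 libraries (0.253 over the 257 genes with the component removed). The transduced copy as the only source is argued against, since CYP2D7 made up 37.5% of the CYP2D6 and CYP2D7 counts of the 2 libraries, and 0.101% of the 990.0 pairs of transduced libraries had a share as high. Expression of the cells' own gene stays open, with a share of 50.0% in other parental libraries and 23.2% expected of the mix, and these shares rest on few counts that need not be separate molecules. Without these 2 libraries 128 genes were called for DMSO in fresh cells in place of 261.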

How the results depend on the processing

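Tests chosen only after the result was seen were the covariate, RLE and DESeq2 without the 3 nearly empty libraries, the fits without the 2 parental libraries with 10 CYP2D6 counts each and without parental progenitor day 14 replicate a, and the 3 added comparisons. No named gene or list that was called changed direction in any alternative. Of 341 named calls, 337 were kept with RLE, 335 with no filter, 338 of 338 with a mean count of at least 10 (which removes CYP2D6) and 339 with the replicate block. Leaving libraries out kept 280, 287 and 318 without replicate a, b and c, 340 without the nearly empty libraries, 329 without the 2 parental libraries, 338 without progenitor day 14 replicate a, and 323 with only the compared libraries. The covariate kept 335 and DESeq2 301, and 341 with RLE and 339 with DESeq2 when the nearly empty libraries were also left out. Of 190 list calls between 167 (without replicate a) and 190 (replicate block) were kept with edgeR settings, and of the 147 list calls of planned comparisons 96 were kept with the estimated correlation. CYP2D6 was called in 15 of 15 conditions in every setting that tested it. In simulated data for genotype in fresh cells 23.3% of genes changed by 1.3 times were recovered.

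Counts that moved by more than 1.5 times follow, and the cause was not tested unless given. With RLE, genotype gave 286 calls in progenitors, 637 in fresh and 472 in thawed cells, DMSO in thawed cells 1705, and the difference of DMSO effects 5. Without the nearly empty libraries RLE gave 16 for the last and stayed within 1.5 times elsewhere, so the other RLE moves went with those libraries. No filter gave 106 for genotype in progenitors and 4 for the difference of DMSO effects, and a mean count of at least 10 gave 4. Leaving out the nearly empty libraries gave 15 for that difference, and DESeq2 without them 15. The covariate gave 269, 606 and 425 for genotype in progenitors, fresh and thawed cells, 821 for thawed against fresh and 19 for the difference of DMSO effects. Without the 2 parental libraries there were 128 for DMSO in fresh cells and 0 for the difference of DMSO effects, with fewer libraries. Fits to the compared libraries only gave 36 and 480 for genotype in progenitors and thawed cells, 752 for progenitor day 14 against day 0, 1422 for DMSO in thawed cells and 31 for the difference of DMSO effects. DESeq2 gave 26, 225 and 157 for genotype, 795 for progenitor day 14, 1237 for differentiated against progenitor, 88 for DMSO in fresh cells, 851 and 706 for day 44 in fresh and thawed cells, 73 for the difference of genotype effects, 0 for that of DMSO effects and 766 for day 32 against day 30 in thawed cells.

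Leaving out replicate a, b or c of every group, or parental progenitor day 14 replicate a alone, left fewer libraries. The lowest and highest counts were, for genotype in progenitors 36 to 169, in fresh cells 81 to 403 and in thawed cells 60 to 268. Progenitor day 14 had 673 to 1146 and differentiated against progenitor 870 to 1896. DMSO in fresh cells had 103 to 261 and in thawed cells 291 to 825. Day 44 in fresh cells had 918 to 1447 and in thawed cells 721 to 1192. Thawed against fresh had 209 to 1467. The difference of genotype effects between fresh cells and progenitors had 24 to 189, that between thawed and fresh cells 0 to 0, and the difference of DMSO effects 0 to 3. Day 32 against day 30 in fresh cells had 672 to 2100 and in thawed cells 764 to 1375, and progenitor day 2 against day 0 had 2312 to 3783.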

Other observations

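The 3 comparisons here and the gene-by-gene look at shared genotype calls and at a single library were chosen only after the result was seen.

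Between day 30 and day 32 without DMSO, fresh cells lost P450 transcripts, and the immediate-early genes FOS and FOSB were among the largest falls. FOS, an immediate-early transcription factor, fell 48.3-fold (log2 −5.59 ± 0.398, edgeR adjusted p = 1.9e-17), from a mean of 86.7 CPM (n = 5) to 1.99 CPM (n = 6). FOSB fell 53.2-fold (log2 −5.73, and −7.56 without replicate b), IGFBP1 16.8-fold and ATF3 14.5-fold. CYP3A4 fell 6.92-fold (log2 −2.79 ± 0.235, edgeR adjusted p = 1.3e-14), to a mean of 245 CPM from 1742 CPM. The fall was not limited to cells without DMSO. With DMSO at day 32 CYP3A4 was 501 CPM in parental and 417 CPM in transduced cells, against 2460 and 1264 CPM at day 30. The mean log2 level of other P450 enzymes in parental cells was 1.08 at day 30, and 0.15 without and 0.21 with DMSO at day 32. In transduced cells it was 0.64, −0.03 and −0.05. S100A2, a calcium-binding protein, rose 5.50-fold and SPINK1 rose 3.20-fold. Other P450 enzymes had 11 members down (13 when adjusted over the list alone), secreted proteins 1 up and 25 down and ribosomal proteins 34 up (37 when adjusted over the list alone), each called with either correlation. In total 1105 genes rose and 993 fell. Chance in the assignment of libraries is argued against, since 1 of 100 splits, the lowest share possible, gave as many calls as the real 2457. The highest other gave 730.

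Thawed cells over the same 2 days lost P450 transcripts too, with 12 of 22 members down and 2 up, and gained cell cycle transcripts. FOS fell 92.5-fold (log2 −6.53 ± 0.395, edgeR adjusted p = 6.5e-21), CXCL8, the gene of interleukin-8, 25.1-fold (log2 −5.44 without replicate c) and EGR1 23.7-fold. CYP3A4 fell 7.86-fold (log2 −2.97 ± 0.234, edgeR adjusted p = 5.5e-16), to a mean of 174 CPM from 1403 CPM. With DMSO at day 32 it was lower than at day 30 as well, at 568 against 1750 CPM in parental and 502 against 1057 CPM in transduced cells. S100A2 rose 9.03-fold, the matrix proteoglycan DCN 6.64-fold and SPINK1 3.59-fold. Cell cycle genes had 18 members up (28 when adjusted over the list alone), with MCM7 at 2.33-fold and MKI67 at 2.30-fold, and secreted proteins had 1 up and 18 down. In total 667 genes rose and 716 fell, and chance in the assignment of libraries is argued against (1683 calls in the real split, 166 in the highest other).

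Progenitors gained cell cycle transcripts and lost acute phase transcripts from day 0 to day 2. ANLN, a protein of the dividing cell's furrow, rose 12.2-fold (log2 3.61 ± 0.286, edgeR adjusted p = 3.2e-21), CCNB1 7.43-fold (log2 2.89, and 3.53 without replicate a) and CDK1 5.35-fold, and 35 of 37 cell cycle genes rose. FOS fell 124-fold (log2 −6.96 ± 0.431, edgeR adjusted p = 1.4e-21), EGR1 70.4-fold, LBP 14.6-fold, the fibrinogen gene FGG 12.6-fold and the serum amyloid SAA1 12.1-fold. Acute phase genes had 1 member up and 22 down, and secreted proteins 29 down. In total 1715 genes rose and 2050 fell, and chance in the assignment of libraries is argued against (3096 calls in the real split, 1157 in the highest other).

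At all 3 statuses 15 genes were higher and 2 lower in the transduced line. After CYP2D6 the largest change was that of LOC101929829, a transcribed pseudogene of chromosome 22, with log2 fold changes of 3.88, 3.68 and 3.66 in progenitors, fresh and thawed cells, and whether it takes reads of CYP2D6 was not tested. HBE1, embryonic globin, had log2 fold changes of 2.53, 2.55 and 1.36 in progenitors, fresh and thawed cells, and its neighbour OR51B5 had 1.35, 1.49 and 1.08. HBE1 lies at 5268345 and OR51B5 starts at 5340318 on chromosome 11. GPNMB had 1.00, 1.44 and 1.59, PHACTR3 0.72, 1.27 and 0.88, and IGFBP4 −0.59, −0.42 and −0.44. Whether these go with CYP2D6, with the place of insertion or with the history of the line was not tested.

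Parental progenitor day 14 replicate a lay at 0.393 (quartiles 0.271 and 0.478, 24 genes) between the transduced day 14 progenitors, at 0, and parental fresh cells of day 30, at 1, where replicate b lay at −0.00945. Its CYP2E1 stood at 70.6 CPM against 9.26 CPM in replicate b, its GPX2 at 91.9 against 20.2 and its ATF3 at 65.7 against 2.53. Its CYP3A4 of 822 CPM lay between group means of 568 and 1057 CPM in the series, but CYP2E1 stood at 186 and 193 CPM in those groups, so no group matched it in both. CPM of single libraries here are without TMM factors, unlike the group means. A mix of RNA and a different culture state were not told apart.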
